A study of Mus musculus with 8 samples.

How the data were processed

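The data are RNA sequencing libraries from 8 mouse adrenal glands, 1 per animal, in 4 groups of genotype and treatment with 2 animals each. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase I, first strands were primed with oligo-dT and random hexamers, libraries were made with a directional NEBNext Ultra kit, and single reads of 75 bases were sequenced on a NextSeq 500. The submitters' processing notes name FastQC (version 0.11), TopHat2 (2.0.13), Bowtie2 (2.2.5.0), Partek (6.6) and the genome build mm10, with no order or settings. For each RefSeq transcript the authors deposited an estimated count of reads and an RPKM value, per the file headers. The estimated counts are not all whole numbers.

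The estimated counts of the 28678 transcripts listed were summed per gene symbol to 18846 genes (5323 with more than 1 transcript) and rounded to whole numbers, and library sizes were taken from these sums. The RPKM column was used only to check the scale of the counts between libraries, which differed from the ratio of the listed totals by at most 2.07%. Gene positions were taken from the RefSeq annotation of mm10, in which 18680 symbols (99.1%) were found. Estimated counts per library ranged from 8020111 to 29568950, a ratio of 3.69, and intervals and floors (3 counts) cover counting error only. No pair of libraries agreed within sampling noise (Pearson correlation 0.808 to 0.974, lowest median chi-square ratio 22.0). Reads from near-identical genes such as Siah1a and Siah1b, and from overlapping genes, are reported as uncertain, since the handling of strand and of reads with several matches is not given in the sources used here.

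Groups and sex were taken from the labels. Genes were kept by edgeR's filterByExpr (minimum count 10), which left 15361 genes and removed 3485, and counts were scaled by TMM factors (0.888 to 1.065). Changes were tested with edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) in 1 model of all 8 libraries with genotype, treatment and sex (4 residual degrees of freedom) for the 3 average comparisons, and in models with 1 interaction (3 residual degrees of freedom) for the comparisons within a treatment or a genotype and for the 3 interactions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the F statistic. Levels are CPM of the filtered, TMM-scaled libraries. Matched pairs are animals that share the labels of the other factors.

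The members of 25 gene lists were fixed before the data were examined: SIAH family, steroidogenic core, zona glomerulosa, X-zone, capsule with Hedgehog and WNT zonation, chromaffin medulla, immediate early and cAMP response, glucocorticoid-responsive, cholesterol synthesis and LDL uptake, hypoxia, circadian clock, ER stress and heat shock, PIAS1 and SUMO pathway, proliferation, macrophage, lymphocyte, neutrophil, adipocyte, endothelial, erythroid, Schwann, fibroblast, muscle, kidney with liver and pancreas, and Y-linked genes with Xist. All 25 had at least 3 tested members. Each list was tested in 4 comparisons with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 25 lists of a comparison, with camera at an estimated correlation and fry beside it. "Adjusted over the list alone" means Benjamini-Hochberg over the members of that list. Counts and medians cover all tested members, and some single members are not reported here.

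Genes were named by a rule fixed before the data were examined. It took the SIAH genes. For each average comparison it took up to 10 called genes with the highest and 10 with the lowest log2 fold change that had the same sign in all 4 matched pairs and a mean log2 CPM of at least 1. For the other comparisons it took up to 5 called genes in each direction, or, where fewer than 3 were called, the 5 smallest p-values, stated not to pass. From each list it took up to 4 called members, or up to 2 members with the highest mean CPM where none was called. Members that passed over the list alone (up to 4 per list) were an addition made after the data were seen, as were the genes named to describe kidney, liver and neuronal transcripts and sex.

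Alternatives fixed before the data were examined were RLE size factors, no filter on low counts, DESeq2 (1.42.0), limma-voom, models with an interaction for the averages, no sex covariate, the 4 libraries of a treatment alone, each library left out in turn, and the set tests named above. Alternatives added after the data were seen left out 2 wild-type libraries that held kidney or liver transcripts, used edgeR's robust fit or limma-voom with sample weights, and left out genes at least 8 times higher in 1 library than in every other, alone and in combination. Pseudocount settings planned for normalized values were not needed, since the values are counts. The scripts were tested on simulated data in which 100 genes were changed 2-fold and 100 genes 4-fold. For the average comparison of genotypes edgeR recovered 3.2% of 2-fold and 42.7% of 4-fold changes with 6 false calls among 50, DESeq2 26.3% and 70.8% with 67 false among 160, and limma-voom 8.4% and 49% with 5 false among 60. For genotypes in untreated animals edgeR recovered 0% and 4% with 3 false calls among 7, and for the interaction of genotype and treatment 0% and 0%, with all 6 calls false. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the tables and plots.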

Results

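Messenger RNA was measured by sequencing in 8 mouse adrenal glands, 1 gland per library and 1 animal per combination of genotype, treatment and sex. The genotypes were wild type and Siah1a−/−, a knockout of an E3 ubiquitin ligase of the SIAH family, and all animals carried the strain label 129SVEV. In each genotype, 2 animals were untreated and 2 had received adrenocorticotropic hormone (ACTH), the pituitary peptide that drives glucocorticoid synthesis in the adrenal cortex, by intraperitoneal injection at 100 µg/kg 1 hour before harvest. Each of these 4 groups held 1 animal labelled male and 1 labelled female. The title of the series names adrenal organization and hyperaldosteronism as the subject of the study. The total of estimated counts ranged from 8020111 to 29568950 per library. The untreated wild-type libraries held 8020111 (labelled male) and 17520051 (labelled female), the untreated knockout libraries 15182870 and 11964373, the ACTH-treated wild-type libraries 24085448 and 29568950, and the ACTH-treated knockout libraries 14303494 and 13144910, in the same order. Levels are given below as CPM (counts scaled to a common library total) of each library, scaled by the TMM factors, with the SD over animals.

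Transcripts of the sex chromosomes went against 1 label. The library labelled untreated wild-type male held Xist, the X-inactivation RNA of female cells, at 388 CPM, between the 253 and 761 CPM of the 4 libraries labelled female, and the 3 other libraries labelled male held 4.05, 5.98 and 31.8 CPM. The same library had no counts of the Y-linked genes Kdm5d, Uty and Eif2s3y, which allows up to 0.353 CPM (3 counts, counting error only), and its Ddx3y level was 3.06 CPM against 311 to 376 CPM in the other libraries labelled male. It is called the library labelled untreated wild-type male throughout. Pairs were matched by label, so the untreated pair labelled male sets this library against a knockout library with 570 CPM of these Y-linked genes together. By these transcripts that pair is not matched for sex, which limits statements about all 4 matched pairs. The label was kept in all fits, and no fit with it changed was run. The ACTH-treated wild-type library labelled female held 23.5 CPM of these 4 Y-linked genes together (Ddx3y 13.25 CPM, Eif2s3y 7.07 CPM), the other 3 libraries labelled female held 0 to 3.91 CPM, and the 3 other libraries labelled male 490 to 605 CPM. The 31.8 CPM of Xist belonged to the ACTH-treated wild-type library labelled male. The library labelled untreated wild-type male also held kidney transcripts, with the phosphate transporter Slc34a1 at 600.5 CPM, Kap at 304 CPM and uromodulin (Umod) at 241 CPM, while no other library exceeded 4.88 CPM for any of these 3 genes. The ACTH-treated wild-type library labelled female held liver transcripts, with albumin (Alb) at 34060 CPM, Trf at 10950 CPM, Ahsg at 8923 CPM and Apoa1 at 3620 CPM. The highest Alb level among the other 7 libraries was 358 CPM. The ACTH-treated knockout library labelled male held the neuronal gene Stmn2 at 184 CPM, and no other library exceeded 21.5 CPM. Counts of changed genes are also given below without the wild-type libraries that held kidney or liver transcripts (2 of the 4), a setting chosen after the data were seen.

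Siah1a (chromosome 8, 86720454 to 86746006, mm10) was still counted in the knockout. It stood at 26.3 and 26.1 CPM in the untreated wild-type libraries and 33.1 and 32.4 CPM in the ACTH-treated ones (labelled male, then female), and at 25.2 and 21.2 CPM in the untreated knockout and 19.0 and 17.4 CPM in the ACTH-treated knockout. The means were 29.5 ± 3.78 CPM in wild type and 20.7 ± 3.38 CPM in the knockout (SD, n = 4), and the knockout was lower in all 4 pairs of animals matched for sex label and treatment. The log2 fold change of -0.52 (SE 0.23) did not pass over all genes in edgeR's quasi-likelihood test (adjusted p = 0.383). The files give 1 sum per gene and not which exons the reads covered, and the paralog Siah1b is similar enough in sequence that reads could be shared between them, so these values do not show whether the targeted part was transcribed. Siah1b (chromosome X, 164070703 to 164076493) averaged 3.46 ± 1.68 CPM in wild type and 3.06 ± 2.12 CPM in the knockout. Siah2 (chromosome 3, 58674949 to 58692439) averaged 19.6 ± 12.5 CPM and 25.7 ± 8.75 CPM, with 1.41 CPM in the library labelled untreated wild-type male and 21.5 to 27.9 CPM in the other 3 wild-type libraries.

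The first comparison set the 4 libraries labelled Siah1a−/− against the 4 of wild type, averaged over treatment and sex label. Genes of cholesterol synthesis were lower in the knockout. Of 24 measured members of the list of cholesterol synthesis and LDL uptake, 21 fell when adjusted over the list alone, 3 did not pass, and 0 passed over all genes. Hmgcs1, the cytosolic HMG-CoA synthase, fell from 928 ± 75.9 CPM in wild type to 385 ± 63.4 CPM in the knockout (SD, n = 4), a log2 fold change of -1.28 (SE 0.16). Fdps fell from 606 ± 172 to 117 ± 51.1 CPM (log2 fold change -2.45, SE 0.36) and Idi1 from 555 ± 129 to 148 ± 62.6 CPM (-1.96, SE 0.30). Each of these 3 was lower in the knockout in all 4 matched pairs. Among the members that did not pass were Srebf2 and Dhcr7, the latter at 707 ± 100.3 CPM in wild type and 878 ± 298 CPM in the knockout. The median log2 fold change of the list was -1.22 (camera, adjusted p = 6.43e-15 with the preset correlation, adjusted p = 0.365 with an estimated correlation), and fry gave an adjusted p of 0.0424. The adipocyte list lay lower in the knockout on average as well (median -0.97), with 0 members passing. In the ACTH-treated pair labelled female, however, the adipocyte median was 0.46 and the cholesterol median -1.5.

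**Figure D1:**
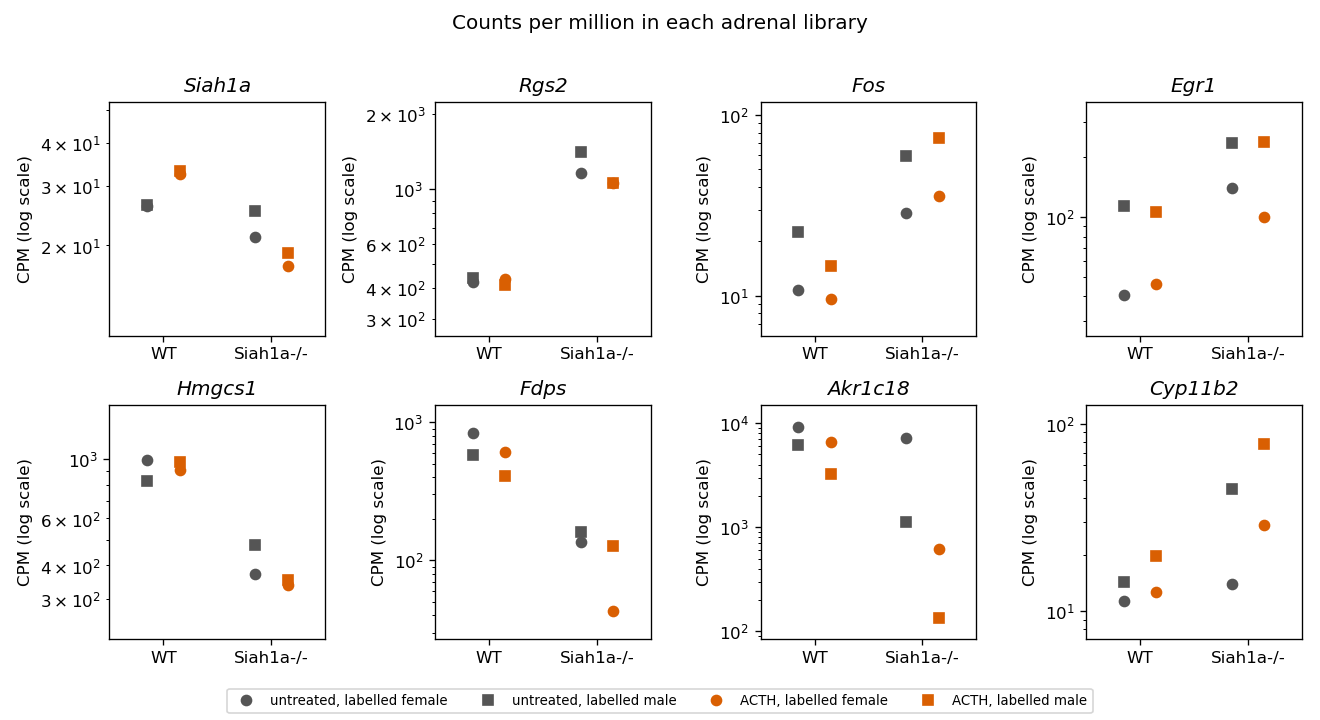
CPM (log scale) of 8 genes in each of the 8 libraries, with wild type and Siah1a−/− on the horizontal axis. Circles are animals labelled female, squares animals labelled male, grey is untreated and orange is ACTH. Rgs2 lay between 413 and 439 CPM in wild type and between 1059 and 1405 CPM in the knockout, and Hmgcs1 lay between 830 and 995 CPM in wild type and between 339 and 478 CPM in the knockout.

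Immediate early genes and genes that respond to cAMP were higher in the knockout. Rgs2, a regulator of G-protein signalling, rose from 428 ± 12.0 to 1171 ± 163 CPM, a 2.72-fold difference (log2 fold change 1.45, SE 0.14) that passed over all genes (edgeR, adjusted p = 0.0381) and was seen in all 4 matched pairs. Of 36 measured members of this list, 16 rose when adjusted over the list alone, 20 did not pass, and 1 (Rgs2) passed over all genes. Fos rose from 14.4 ± 5.80 to 49.4 ± 21.0 CPM (log2 fold change 1.75, SE 0.23), Egr1 from 76.7 ± 38.7 to 178 ± 69.1 CPM (1.28, SE 0.16), and Dusp1 from 41.4 ± 5.37 to 82.9 ± 22.1 CPM (0.99, SE 0.17). The list's median was 1.03 (camera, adjusted p = 2.92e-11; adjusted p = 0.365 with an estimated correlation; fry, adjusted p = 0.0424). Among 18 glucocorticoid-responsive genes, 3 rose when adjusted over the list alone and 0 over all genes. These were Ddit4 (50.4 ± 6.09 to 93.4 ± 17.1 CPM), Nfkbia (111 ± 13.3 to 175 ± 21.5 CPM) and Sgk1 (219 ± 67.6 to 362 ± 113 CPM), with a list median of 0.42 (camera, adjusted p = 0.00134; adjusted p = 0.365 with an estimated correlation). The number of immediate early members that rose was 9 without the ACTH-treated knockout library labelled female and 10 without the untreated knockout library labelled male. The camera call of the glucocorticoid list was lost without the untreated wild-type library labelled female (adjusted p = 0.056).

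Markers of the X-zone, a transient inner cortical zone of the mouse adrenal, were lower in the knockout. Of 5 measured members, 4 fell when adjusted over the list alone and 0 over all genes. Akr1c18, a 20α-hydroxysteroid dehydrogenase, averaged 6325 ± 2458 CPM in wild type and 2267 ± 3304 CPM in the knockout (log2 fold change -2.73, SE 0.66), Pik3c2g 357 ± 176 and 37.6 ± 66.8 CPM (-5.52, SE 1.17), Abcb1b 3634 ± 1095 and 1041 ± 348 CPM (-1.84, SE 0.28), and Thrb 157 ± 30.7 and 72.0 ± 39.8 CPM (-1.28, SE 0.25). Each was lower in all 4 matched pairs. The untreated knockout library labelled female held 7186 CPM of Akr1c18, within the 3266 to 9273 CPM of the wild-type libraries. The other knockout libraries held 134 to 1129 CPM. The list median was -1.84 (camera, adjusted p = 0.00495; adjusted p = 0.365 with an estimated correlation; fry, adjusted p = 0.0605). The camera call was lost without the untreated knockout library labelled male (adjusted p = 0.0602), while 4 members still fell over the list alone. Genes of cell proliferation were lower as well: 6 of 22 members fell when adjusted over the list alone, 16 did not pass, and 0 passed over all genes. Top2a averaged 77.8 ± 17.0 CPM in wild type and 31.4 ± 27.8 CPM in the knockout, Mcm5 31.8 ± 6.23 and 10.8 ± 5.18 CPM, Rrm2 34.5 ± 27.5 and 11.7 ± 9.14 CPM, and Cdc20 18.7 ± 8.94 and 5.46 ± 5.44 CPM. Here the median was -1.51 (camera, adjusted p = 1.53e-09; adjusted p = 0.365 with an estimated correlation), and the number of members that fell ranged from 0 without the untreated knockout library labelled female to 14 without the ACTH-treated knockout library labelled female.

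In the zona glomerulosa list, which includes the aldosterone synthase Cyp11b2, 4 of 20 members rose when adjusted over the list alone, 16 did not pass, and 0 passed over all genes. Cyp11b2 averaged 14.5 ± 3.63 CPM in wild type and 41.4 ± 27.6 CPM in the knockout (log2 fold change 1.29, SE 0.30). The angiotensin receptors Agtr1a (150.2 ± 57.2 and 350.0 ± 116 CPM; log2 fold change 1.18, SE 0.33) and Agtr1b (12.5 ± 6.43 and 29.2 ± 16.5 CPM; 1.23, SE 0.34) and the nuclear receptor Nr4a1 (475 ± 170.1 and 1445 ± 523 CPM; 1.56, SE 0.28) completed these 4, and Nr4a1 also belongs to the immediate early list. The list median was 0.41 (camera, adjusted p = 0.00171; adjusted p = 0.512 with an estimated correlation). Without the 2 wild-type libraries that held kidney or liver transcripts, 1 member rose over the list alone and the camera adjusted p was 0.0515. Without the ACTH-treated knockout library labelled female 0 members rose and the camera adjusted p was 0.0842, and without the untreated knockout library labelled male 0 members rose. The steroidogenic core as a list did not pass (camera, adjusted p = 0.193, 24 members), and its median of 0.08 and mean of -0.07 differed in sign. Within it Akr1b7 (6509 ± 1715 to 17840 ± 7695 CPM), Fdx1 (1848 ± 153 to 3759 ± 891 CPM) and Scarb1 (2151 ± 699.8 to 4881 ± 2375 CPM) rose over the list alone, and Stard4, also in the cholesterol list, fell from 46.2 ± 7.47 to 10.2 ± 5.08 CPM. Star, which carries cholesterol into mitochondria, stood at 14530 ± 3540 and 15570 ± 2547 CPM.

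In the list of chromaffin cells of the medulla 1 of 25 members rose over the list alone, Penk, from 14.7 ± 6.53 to 47.5 ± 16.4 CPM, and the median was 0.93 (camera, adjusted p = 1.38e-05; adjusted p = 0.587 with an estimated correlation). The matched pairs had medians of 1.91 and 0.71 untreated and 1.16 and -0.32 after ACTH (labelled male, then female). The pair with 1.91 is the one not matched for sex by its transcripts, and this list lay lower in libraries labelled female (median -0.78). Without the ACTH-treated knockout library labelled female 17 members rose. Chgb averaged 1531 ± 479 and 2711 ± 1225 CPM and Chga 867 ± 238 and 1800 ± 828 CPM. The adipocyte list had a median of -0.97 (camera, adjusted p = 0.00539; adjusted p = 0.750 with an estimated correlation) with 0 of 18 members passing, Scd1 at 3389 ± 3092 and 693 ± 674 CPM and Fabp4 at 1884 ± 676 and 2228 ± 841 CPM. Its median was 0.46 in the ACTH-treated pair labelled female, and -0.72, -0.79 and -2.9 in the other pairs. The ER stress and heat shock list (median 0.41, adjusted p = 0.00477; 0.512 with an estimated correlation) and the PIAS1 and SUMO list (median 0.19, adjusted p = 0.0449; 0.365 with an estimated correlation) passed camera with 0 members passing alone. The ER stress call was lost without the untreated wild-type library labelled female (adjusted p = 0.056) or the ACTH-treated one labelled male (adjusted p = 0.107). Hspa8 averaged 2048 ± 330.1 and 2983 ± 579 CPM, and Sumo2 220 ± 21.1 and 254 ± 23.1 CPM. The PIAS1 and SUMO call was lost when any library but the ACTH-treated wild-type library labelled male was left out, and the adipocyte call without the library labelled untreated wild-type male, the ACTH-treated knockout library labelled male or the ACTH-treated wild-type library labelled male. The 15 remaining lists did not pass camera, with adjusted p from 0.0646 to 0.938. Of these, the endothelial list had 2 members that rose over the list alone, Cldn5 (47.5 ± 9.22 to 96.8 ± 22.9 CPM) and Gpihbp1 (26.8 ± 7.49 to 50.4 ± 7.64 CPM). The hypoxia list had Ddit4 higher and Eno1 lower (105 ± 13.7 to 60.9 ± 15.6 CPM). The SIAH, capsule and Hedgehog, circadian, macrophage, lymphocyte, neutrophil, erythroid, Schwann, fibroblast, muscle, kidney and liver, and sex-chromosome lists had 0 members passing.

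**Figure D2:**
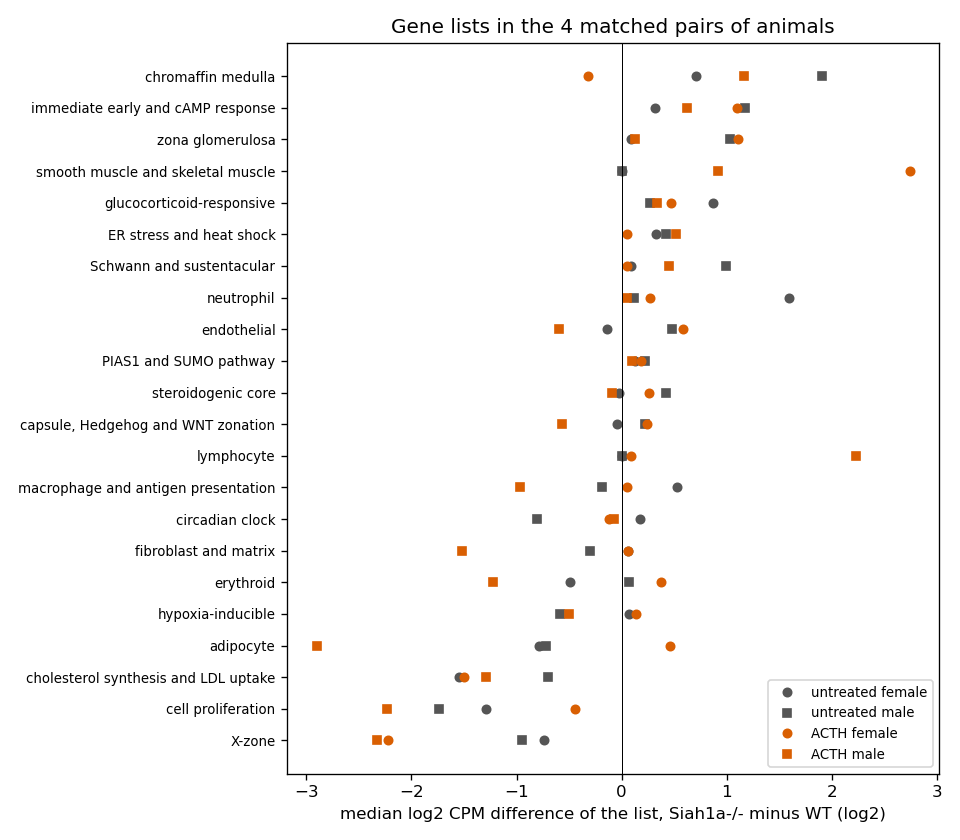
Median log2 CPM difference of each gene list, knockout minus wild type, in the 4 pairs of animals matched for sex label and treatment (horizontal axis in log2 units, 1 row per list). The cholesterol list lay between -1.55 and -0.70 and the X-zone list between -2.33 and -0.74 in the 4 pairs, and the immediate early list lay between 0.32 and 1.17.

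Over all 15361 tested genes, 4 passed in edgeR, 1 higher and 3 lower, and 2065 had an unadjusted p under 0.05. Other ways to split the 8 libraries into 4 and 4 gave from 53 to 2338 genes at that unadjusted p. The 3 lower genes, named after their values were seen, were the liver genes Hc, Cyp2c50 and Azgp1, at 394, 121 and 293 CPM in the ACTH-treated wild-type library labelled female and at no more than 3.68 CPM in any other library. DESeq2 called 947 genes and limma-voom 108, of which 4 and 1 were among the edgeR calls. Without the 2 wild-type libraries edgeR called 3 genes, with 0 shared, and leaving out single libraries gave from 0 (without the ACTH-treated knockout library labelled female) to 253 (without the untreated wild-type library labelled female). The call of Rgs2 was lost when any knockout library or the ACTH-treated wild-type library labelled female was left out, at log2 fold changes of 1.35 to 1.5.

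The second comparison asked what changed 1 hour after ACTH, averaged over genotype and sex label. The controls were untreated and no vehicle injection is among the labels. Effects of injection and handling can therefore not be told apart from those of ACTH, here and within each genotype. Immediate early genes were higher after ACTH, and 8 of 36 members rose when adjusted over the list alone, 28 did not pass, and 0 passed over all genes. Among other splits of the 8 libraries into 4 and 4, splits with identical values also gave 8 members. Each of those kept most untreated libraries on the same side. The split by genotype gave 13. These splits carry a difference by treatment or genotype, so they do not test chance for this count, which is not excluded. Klf4 rose from 24.1 ± 18.8 CPM in untreated glands to 177 ± 106 CPM after ACTH (SD, n = 4; log2 fold change 3.04, SE 0.50), and the orphan nuclear receptors Nr4a2 from 36.6 ± 52.6 to 277 ± 191 CPM (3.43, SE 0.73) and Nr4a3 from 122 ± 111 to 594 ± 369 CPM (2.43, SE 0.53). Zfp36, which binds AU-rich mRNAs, rose from 20.0 ± 3.95 to 45.6 ± 12.0 CPM (1.17, SE 0.25). Each was higher in all 4 matched pairs. The untreated knockout library labelled male held 115 CPM of Nr4a2, 285 CPM of Nr4a3 and 52.0 CPM of Klf4, and the other 3 untreated libraries held at most 12.1, 84.7 and 16.9 CPM. The list median was 0.75 (camera, adjusted p = 3.00e-08; adjusted p = 0.298 with an estimated correlation; fry, adjusted p = 0.146). It held 3 members that rose without the ACTH-treated knockout library labelled female and 4 without the untreated knockout library labelled female.

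Glucocorticoid-responsive genes were also higher after ACTH, with 7 of 18 members rising over the list alone and 0 over all genes. The metallothionein Mt2 rose from 22.3 ± 8.48 to 131 ± 68.9 CPM (log2 fold change 2.59, SE 0.46), the pyruvate dehydrogenase kinase Pdk4 from 327 ± 123 to 747 ± 276 CPM (1.20, SE 0.26), Cdkn1a from 45.4 ± 23.0 to 131 ± 40.4 CPM (1.62, SE 0.41) and Per1 from 79.7 ± 12.7 to 119 ± 29.1 CPM (0.56, SE 0.15). The list median was 0.63 (camera, adjusted p = 0.0006; adjusted p = 0.298 with an estimated correlation). In the X-zone list 3 of 5 members fell over the list alone, with Akr1c18 at 5943 ± 3458 CPM untreated and 2649 ± 2959 CPM after ACTH, Thrb at 138 ± 45.0 and 91.2 ± 62.2 CPM, and Pik3c2g at 273 ± 247 and 122 ± 166 CPM (list median -0.83, camera adjusted p = 0.0165; adjusted p = 0.469 with an estimated correlation). Without any single knockout library, 0 of the 5 passed over the list alone, and without the ACTH-treated one labelled female the camera adjusted p was 0.0589. Cholesterol synthesis genes did not pass as a list (median -0.02, camera adjusted p = 0.743), and Hmgcs1 averaged 668 ± 293 CPM untreated and 645 ± 347 CPM after ACTH. Neither did the steroidogenic core (median 0.04, adjusted p = 0.579), with Star at 13990 ± 3450 and 16100 ± 2203 CPM.

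Further lists passed camera for ACTH with few members passing. In the ER stress and heat shock list (median 0.30, adjusted p = 0.0247; 0.759 with an estimated correlation) Hspa1b rose from 24.9 ± 9.91 to 48.1 ± 14.8 CPM and Atf4 from 242 ± 37.1 to 378 ± 114 CPM over the list alone. In the proliferation list (median 0.40, adjusted p = 0.0364; 0.815 with an estimated correlation) Rrm2 rose from 13.6 ± 14.6 to 32.6 ± 27.0 CPM. The median of this list turned to -0.06 without the ACTH-treated knockout library labelled female (camera adjusted p = 0.845), and its call was also lost without either untreated library labelled female or the ACTH-treated wild-type library labelled male (adjusted p from 0.14 to 0.42). The ER stress call was lost without any single library labelled female (adjusted p from 0.0605 to 0.342), with 0 members rising. The muscle (median 1.57, adjusted p = 0.00983; 0.298), neutrophil (0.87, adjusted p = 0.0165; 0.324), fibroblast (0.51, adjusted p = 0.0394; 0.815) and lymphocyte (2.25, adjusted p = 0.0478; 0.610) lists passed camera with 0 members passing, the last value of each being the adjusted p with an estimated correlation. The neutrophil call was lost without the untreated wild-type library labelled female (adjusted p = 0.18), the fibroblast call without either untreated wild-type library, the ACTH-treated knockout library labelled female or the ACTH-treated wild-type library labelled male (adjusted p from 0.0843 to 0.606), and the lymphocyte call without any 1 library but the one labelled untreated wild-type male. The 16 remaining lists did not pass camera (adjusted p from 0.0576 to 0.743). Among them, Nr4a2 rose within the zona glomerulosa list, and Kap and Cdh16 passed as lower within the kidney and liver list, both highest in the library labelled untreated wild-type male. Over all genes 3 passed in edgeR, all higher, and 938 had an unadjusted p under 0.05. They were Azgp1, Hc and Cyp2c50, the liver genes of the ACTH-treated wild-type library labelled female, and 0 passed without the 2 wild-type libraries. DESeq2 called 123 genes and limma-voom 3, and limma-voom shared 0 with edgeR. Leaving out single libraries gave from 0 (without the untreated knockout library labelled female) to 23 genes (without the library labelled untreated wild-type male).

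The third comparison set the 4 libraries labelled female against the 4 labelled male. The sex-chromosome genes differed in the direction of the labels although 1 library labelled male went against it. Xist was higher in libraries labelled female (468 ± 222 against 107 ± 187 CPM, SD, n = 4), and Ddx3y (4.44 ± 6.06 against 264 ± 176 CPM), Uty (0.525 ± 0.951 against 35.9 ± 24.4 CPM), Kdm5d and Eif2s3y were lower. All 5 passed when adjusted over the list alone and 0 over all genes (list median -6.12, camera adjusted p = 0.00881; adjusted p = 0.626 with an estimated correlation). Among proliferation genes Rrm2 was higher over the list alone (35.3 ± 26.5 against 11 ± 9.55 CPM), Mki67 stood at 74.7 ± 36.8 against 41.2 ± 33.8 CPM, and the list median was 0.89 (camera, adjusted p = 3.74e-09; 0.626 with an estimated correlation). Egr1 was lower (81.7 ± 47.3 against 173 ± 73.0 CPM), and the immediate early list had a median of -0.30 (adjusted p = 2.05e-05; 0.626 with an estimated correlation). The chromaffin list had a median of -0.78 (adjusted p = 1.66e-09; 0.626 with an estimated correlation), with Chgb at 1791 ± 1102 against 2451 ± 1074 CPM. The capsule and Hedgehog list (median 0.36, adjusted p = 0.0078), the cholesterol list (-0.27, adjusted p = 0.00916) and the ER stress and heat shock list (-0.14, adjusted p = 0.0118, with Hspb1 lower at 22.5 ± 4.92 against 42.2 ± 9.25 CPM) also passed camera. With an estimated correlation the adjusted p was 0.723 for the cholesterol list and 0.626 for the capsule and ER stress lists, and the 18 remaining lists did not pass (adjusted p from 0.127 to 0.917). Leaving out the ACTH-treated knockout library labelled female ended the camera calls of the sex-chromosome, capsule, cholesterol and ER stress lists. The sex-chromosome call was also lost without the ACTH-treated wild-type library labelled male, the capsule call without the untreated wild-type library labelled female, the cholesterol call without either untreated knockout library or the ACTH-treated wild-type library labelled male, and the ER stress call without any untreated library. The X-zone marker Akr1c18 averaged 5914 ± 3714 CPM in libraries labelled female and 2678 ± 2678 CPM in those labelled male and did not pass.

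For the comparison by sex label, edgeR called 4 genes over all genes, all higher in libraries labelled female, and 478 had an unadjusted p under 0.05. These were Azgp1, Hc, Cyp2c50 and Selenbp2, and the last stood at 74.3 CPM in the ACTH-treated wild-type library labelled female and at no more than 1.23 CPM elsewhere. DESeq2 called 21 genes and limma-voom 0. Without the 2 wild-type libraries 7 genes passed, with 0 shared.

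Within each treatment the genotypes were compared with 2 animals each. In untreated glands Rgs2 averaged 431 ± 11 CPM in wild type and 1282 ± 174 CPM in the knockout (SD, n = 2; log2 fold change 1.57, SE 0.22), Egr1 77.5 ± 52.0 and 188 ± 67.3 CPM, and the retinaldehyde dehydrogenase Aldh1a1 152 ± 61.3 and 46.4 ± 32.3 CPM. These 3, with Tmem27 and Hc, had the smallest p-values, and edgeR called 0 genes (smallest adjusted p = 0.892; 743 genes with an unadjusted p under 0.05; DESeq2 110, limma-voom 0). Tmem27 stood at 294 CPM in the library labelled untreated wild-type male and at no more than 0.712 CPM elsewhere. After ACTH, edgeR called 1 gene, Hc, the liver gene of 1 library, and 1264 genes had an unadjusted p under 0.05 (DESeq2 501, limma-voom 12 with 0 shared). Among the next genes by p, none of which passed, Aldh1a1 averaged 211 ± 98.6 CPM in wild type and 24.9 ± 8.40 CPM in the knockout (log2 fold change -3.04, SE 0.28, adjusted p = 0.0729), and Thrb 144 ± 25.3 and 38.9 ± 2.14 CPM (-1.87, SE 0.21, adjusted p = 0.148). Akr1c6, also among them, was at 431 CPM in the library with liver transcripts and at no more than 2.19 CPM elsewhere. Without the 2 wild-type libraries 0 genes passed in untreated glands and 21 after ACTH.

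Within each genotype the response to ACTH was compared with 2 animals per group. In wild type, Klf4 stood at 14.1 ± 4.0 CPM untreated and 134 ± 3.40 CPM after ACTH, and Nr4a2 at 9.40 ± 3.65 and 157 ± 1.33 CPM (SD, n = 2). In edgeR 0 genes passed (smallest adjusted p = 0.0542; 393 genes with an unadjusted p under 0.05; DESeq2 38, limma-voom 0), and the 5 smallest p-values belonged to Hc, Akr1c6, Hao1 and Cyp2c50, highest in the library with liver transcripts, and to Tmem27. In the knockout the 5 smallest p-values belonged to Csrnp1, Bhlhe40, Lrrn1, Slc37a2 and Thrb, and 0 genes passed (smallest adjusted p = 0.555; 649 genes with an unadjusted p under 0.05; DESeq2 100, limma-voom 0). Csrnp1 averaged 12.9 ± 4.58 CPM untreated and 79.4 ± 37.7 CPM after ACTH (log2 fold change 2.59, SE 0.31), Bhlhe40 126 ± 27.5 and 37.4 ± 0.758 CPM (-1.73, SE 0.23), and Thrb 105 ± 18.7 and 38.9 ± 2.14 CPM (-1.42, SE 0.20). Without the 2 wild-type libraries 0 genes passed in wild type and 2 in the knockout.

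Interaction terms tested whether these effects differed between groups. For genotype and treatment edgeR called 0 genes (283 with an unadjusted p under 0.05; DESeq2 14, limma-voom 0). The smallest p-values belonged to Akr1c6, Ddx3y, Lrrc19, Fxyd1 and Csrnp1, none of which passed. Csrnp1 stood at 11.5 ± 2.51 CPM in untreated and 16.1 ± 5.53 CPM in ACTH-treated wild type. In the X-zone list Thrb (log2 fold change of the interaction -1.18, SE 0.28) and Akr1c18 (-2.60, SE 0.73) passed over the list alone. Akr1c18 averaged 7728 ± 2184 CPM in untreated and 4922 ± 2342 CPM in ACTH-treated wild type, and 4157 ± 4283 and 376 ± 342 CPM in the knockout. Neither passed without the untreated knockout library labelled female or the ACTH-treated wild-type library labelled male. The X-zone list itself had a camera adjusted p of 0.0532. The lists of chromaffin cells (median -0.47, camera adjusted p = 0.0464), fibroblasts (-0.60, adjusted p = 0.0464) and muscle (0.67, adjusted p = 0.0305) passed camera with 0 members passing, and the sex-chromosome list passed (-11.44, adjusted p = 0.0464) with its 4 Y-linked members lower over the list alone. With an estimated correlation the adjusted p was 0.933, 0.933, 0.883 and 0.883 for these 4 lists in that order, and the other 21 lists had a camera adjusted p from 0.0532 to 0.927. The Y-linked terms follow the library labelled untreated wild-type male, with 3.06 CPM of these genes against 490 to 605 CPM in the others labelled male. Without the library labelled untreated wild-type male, 1 Y-linked member passed. The chromaffin median ran from -1.93 (without the ACTH-treated knockout library labelled male) to 0.23 (without the one labelled female), and the muscle median was -0.17 without the library labelled untreated wild-type male. For genotype and sex label 2 genes passed, Mbl2 and Uox, at 464 and 350.0 CPM in the library with liver transcripts and at no more than 3.70 CPM elsewhere (525 genes with an unadjusted p under 0.05; DESeq2 34, limma-voom 0). For treatment and sex label 25 genes passed (688 with an unadjusted p under 0.05; DESeq2 116, limma-voom 12 with 4 shared), of which 18 were highest in the library with liver transcripts and 7 in the library labelled untreated wild-type male. Habp2 and Saa1, for example, stood at 70.7 and 73.0 CPM in the former, and Cyp4a10, Cyp2j5 and Glyat at 183, 244 and 105 CPM in the latter. Without the 2 wild-type libraries 2, 2 and 4 genes passed for the 3 interactions, with 0 shared.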

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

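The tests of other groupings, of kidney or liver RNA, of female RNA and of the sex label were chosen only after the result was seen, and the test of adipose tissue was chosen before it.

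Cholesterol synthesis genes were lower in the knockout. Among the 35 splits of the 8 libraries into 4 and 4, only the real one (1 split) gave as many members over the list alone, 21 against at most 1, and over all 25 lists the highest count in any other split was 19, in the chromaffin list. This is the smallest share that 35 splits can give. Most other splits are not balanced for treatment and sex label. They keep some or all of any genotype difference within their sides, so they are not equal to the real one. Camera with an estimated correlation did not pass (adjusted p = 0.365). For the median, 3 splits, 2 of them with identical values, gave one of that size (1.22 against at most 1.33). The 2 identical ones each set most wild-type libraries against most knockout libraries. They carry a genotype difference, so they do not decide whether chance gave the median. Chance is not excluded for the count, and these splits leave it undecided for the median. Liver or kidney RNA as the cause is argued against by the median of -1.36 (quartiles -1.66 and -0.95) without the 2 libraries that held it, and adipose tissue by the median of -1.32 (quartiles -1.83 and -0.93) with the adipocyte list as a covariate. The genotype itself may account for the pattern, as a hypothesis. With 1 animal per combination, other differences between these animals, such as feeding, litter or handling, were not tested.

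X-zone markers were lower in the knockout. The real split alone (1 of 35) gave as many members over the list alone, 4 against at most 2, but the list was picked among 25 after its count was seen. Its 4 of 5 members (80%) were matched by the sex-chromosome list in 4 other splits, 2 of them identical (5 splits with the real one, at most 80%). Sex-chromosome genes follow the sex of the animals, and 1 of these splits is the one by sex label. For the median, 4 splits, 2 of them identical, gave that size (1.84 against at most 2.03). Apart from the real one, these set most wild-type libraries against most knockout libraries and carry a genotype difference. Neither comparison tests chance for this list, so that chance is not excluded. Female RNA in libraries labelled wild-type male could raise these markers. In the 2 pairs of animals labelled female the median of all 5 members was -0.74 untreated and -2.22 after ACTH, against -1.84 over all animals. The untreated difference is smaller than the overall one and still below 0. Such RNA could act only in the pairs labelled male (-0.95 untreated and -2.33 after ACTH), which leaves this explanation open for a part of the fall. Liver or kidney RNA is argued against by the median of -2.13 (quartiles -2.88 and -1.32) without the 2 libraries. That setting also leaves out the library labelled untreated wild-type male, with 388 CPM of Xist. Female RNA in that library is thus argued against as the whole cause. The other wild-type library labelled male held 31.8 CPM of Xist. A genotype difference, and a difference in age or reproductive state between animals, which was not tested, stay open.

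The library labelled untreated wild-type male held no Y-linked transcripts beyond traces. A male gland mixed with female RNA is argued against by its Y-linked sum, 0.551% of the mean of the other libraries labelled male. A wrong sex label is consistent with Xist at 82.8% of the mean of libraries labelled female. Whether a label was exchanged with a sample not analysed here stays open, and the values do not show whether its genotype or treatment label is affected. No biological explanation was tested.

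The number of genes called in the 3 average comparisons does not exclude chance: 6 of the 35 splits gave as many for genotype (4 against at most 79), 8 for ACTH (3 against at most 12) and 7 for sex label (4 against at most 23). The 2 splits with 79 genes gave identical values and are 1 fit, as are 2 of the 8 for ACTH. All 6 splits for genotype held the 2 wild-type libraries with kidney or liver transcripts on the same side. In the 2 splits with 79 genes the kidney, liver and pancreas list had the highest share of members passing (45.5%). Other splits with both libraries on the same side gave as few as 0 genes. Apart from the real one, the splits that gave as many for genotype held 3 libraries of 1 genotype and 1 of the other on each side. Genotype may therefore be part of these counts. The cause was not tested. For immediate early genes in the knockout 1 split, the real one, gave as many members of this list (16 against at most 2). In any of the 25 lists 2 splits gave as many (at most 19, in the chromaffin list). For the median, 3 splits, 2 of them identical, gave that size (1.03 against at most 1.17). Apart from the real one, these splits set most wild-type libraries against most knockout libraries. They carry a genotype difference and do not test chance, which is not excluded.

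The following results differed between groups by the interaction term. For genotype and treatment these were Thrb (log2 -1.18) and Akr1c18 (-2.60), adjusted over the list alone. The X-zone list that holds them did not pass camera (adjusted p = 0.0532). Akr1c18 stood at 7186 CPM in the untreated knockout library labelled female and at 1129 CPM in the one labelled male. In the sex-chromosome list (median -11.44) Ddx3y had -7.49, Uty -12.53, Kdm5d -11.44 and Eif2s3y -14.36, and fitted folds of genes with no counts in a library depend on the prior count. The library labelled untreated wild-type male held 3.06 CPM of these genes together, and the other libraries labelled male held 490 to 605 CPM. These terms follow that library and do not show a response to ACTH that differs by genotype. The chromaffin (median -0.47), fibroblast (-0.60) and muscle (0.67) lists passed camera at the preset correlation with 0 members passing, and with an estimated correlation the adjusted p was 0.933, 0.933 and 0.883 (0.883 for the sex-chromosome list). Leaving out single libraries ended the camera call of the chromaffin list for 5 of the 8 libraries, of the fibroblast list for 5, of the muscle list for 2 and of the sex-chromosome list for 7. The chromaffin median was then between -1.93, without the ACTH-treated knockout library labelled male, and 0.23, without the one labelled female, and the muscle median was -0.17 without the library labelled untreated wild-type male. For genotype and sex label 2 genes differed, Mbl2 (-10.04) and Uox (-9.24), both highest in the library with liver transcripts. For treatment and sex label 25 did, among them Habp2 (19.17), Cyp4a10 (17.15), Cyp2j5 (17.02), Saa1 (17.02) and Glyat (16.56). Of these, 18 were highest in the library with liver transcripts and 7 in the library labelled untreated wild-type male, which held kidney transcripts. Without these 2 libraries 2 and 4 genes passed for the 2 interactions, with 0 shared.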

How the results depend on the processing

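Settings that left out 2 wild-type libraries, used a robust fit or sample weights, or left out the 256 genes at least 8 times higher in 1 library than in every other were chosen only after the result was seen. Over all alternatives, no called gene among those followed one by one turned direction. Of the values of these genes 4325 kept their call or stayed within their SE, 302 without a call moved by more than their SE, and 385 lost the call. Of the medians of called lists, 225 stayed, 71 lost the call and 4 turned direction. The cause of these changes was not tested.

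For genotype on average (4 genes), the count was 41 with no filter on low counts, 947 with DESeq2, 108 with limma-voom, 1 with no sex covariate, 22 with the robust fit and 133 with sample weights. It was 9 without genes high in 1 library alone (37 with the robust fit as well), and, without the 2 libraries holding kidney or liver transcripts, 39 with the robust fit and 16 without genes high in 1 library alone. For ACTH on average (3 genes) it was 8 with no filter, 123 with DESeq2, 0 with the interaction in the model, 0 with no sex covariate, 5 with the robust fit and 26 with sample weights. It was 0 without the 2 libraries, 0 without genes high in 1 library alone with either fit or without the 2 libraries as well, and 5 with the robust fit without the 2 libraries. For sex label (4 genes) it was 7 with no filter, 21 with DESeq2, 0 with limma-voom, 7 with the interaction in the model and 54 with sample weights. It was 7 without the 2 libraries, 0 without genes high in 1 library alone with either fit, and 7 with both changes.

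For genotype in untreated animals (0 genes) DESeq2 gave 110 and the 4 libraries alone 27. For genotype after ACTH (1 gene) the count was 11 with no filter, 501 with DESeq2, 12 with limma-voom, 0 with no sex covariate, 26 with the 4 libraries alone and 21 without the 2 libraries. For ACTH in wild type (0 genes) it was 7 with no filter and 38 with DESeq2, and for ACTH in the knockout (0 genes) 100 with DESeq2 and 2 without the 2 libraries. For genotype and treatment (0 genes) it was 14 with DESeq2 and 2 without the 2 libraries, for genotype and sex label (2 genes) 34 with DESeq2 and 0 with limma-voom, and for treatment and sex label (25 genes) 116 with DESeq2, 12 with limma-voom and 4 without the 2 libraries.

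Leaving out each library in turn gave 0 to 253 genes for genotype, 0 to 23 for ACTH, 1 to 25 for sex label, 0 to 95 for genotype in untreated animals, 0 to 173 for genotype after ACTH, 0 to 70 for ACTH in wild type, 0 to 0 for ACTH in the knockout, 0 to 11 for genotype and treatment, 0 to 29 for genotype and sex label and 0 to 91 for treatment and sex label. A group left with 1 library was assumed to vary like the others. Lists called by camera numbered 9 to 11 for genotype (10 with all libraries), 5 to 13 for ACTH (9), 5 to 9 for sex label (7) and 0 to 8 for genotype and treatment (4, and 9 without the 2 libraries). With an estimated correlation 0 lists were called in each of the 4 comparisons, and fry called 2, 0, 0 and 0. The proliferation list after ACTH had medians from -0.06, without the ACTH-treated knockout library labelled female, to 0.81 when single libraries were left out. The chromaffin list in the interaction of genotype and treatment had medians from -1.93 to 0.23 when single libraries were left out (0.23 without the ACTH-treated knockout library labelled female), -0.10 without the library labelled untreated wild-type male, where camera's direction turned, and 0.37 without the 2 libraries.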

Other observations

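The tests of fatty acid synthesis, with adipose tissue as its cause, and of ribosomal protein genes were chosen only after the result was seen, and those of oxidative phosphorylation, of the proteasome and of genes near Siah1a were chosen before it.

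Genes of cytosolic ribosomal proteins were higher in the knockout. Of 78 tested, 77 had a log2 fold change above 0 and 69 rose when adjusted over the group alone, with a median of 0.56 (camera with an estimated correlation, adjusted p = 0.00472; fry, adjusted p = 7.54e-05; adjusted over the 4 groups tested here). The median was above 0 in all 4 matched pairs and lay between 0.53 and 0.57 when single libraries were left out. Rpl12 had a log2 fold change of 0.75 (SE 0.14) and Rpl10 of 0.59 (SE 0.13), and neither passed over all genes. A shift by genotype is consistent with these values as a hypothesis found and tested on the same data, and RNA quality and reads from processed pseudogenes were not tested.

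Genes of fatty acid synthesis were mostly lower in the knockout. Of 16 tested, 10 fell when adjusted over the group alone, with a median of -0.83 (camera, adjusted p = 2.43e-06; adjusted p = 0.179 with an estimated correlation; fry, adjusted p = 0.0281). The fatty acid synthase Fasn had a log2 fold change of -3.72 (SE 0.48), Acss2 of -2.39 (SE 0.33), Acaca of -2.09 (SE 0.31) and Gpam of -1.55 (SE 0.24), and none passed over all genes. Acly had 0.00 (SE 0.23). The adipocyte list moved the same way on average (median -0.97) and shares Scd1 and Thrsp with this group. Its median was -0.72 and -0.79 in the untreated pairs (labelled male, then female), and -2.90 and 0.46 in the ACTH-treated ones. The fatty acid median was above 0 in 0 of the matched pairs. With the other adipocyte members as a covariate the median was -0.57 (quartiles -1.35 and -0.35), which argues against adipose tissue as the whole cause and leaves a part open. A joint shift by genotype may be at work and stays open, since fry passed and camera with an estimated correlation did not.

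Of the 39 proteasome subunit genes, 34 had a log2 fold change above 0 and the median was 0.32, with 0 passing over the group alone (camera, adjusted p = 1.59e-06; adjusted p = 0.195 with an estimated correlation; fry, adjusted p = 0.0469). The median was above 0 in all 4 matched pairs and lay between 0.19, without the ACTH-treated knockout library labelled male, and 0.36 when single libraries were left out. These values leave a shift by genotype open. The 77 genes of oxidative phosphorylation had a median of -0.13 (quartiles -0.27 and 0.03), under the 0.1 set as the limit for a joint rise. It was above 0 in 2 of the 4 pairs, 0.03 without the 2 wild-type libraries that held kidney or liver transcripts, and from -0.28 (without the untreated wild-type library labelled female) to 0.09 (without the library labelled untreated wild-type male) when single libraries were left out. This argues against a joint rise above that limit, and the sign of the median is not settled.

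Genes within 10 Mb of Siah1a were examined for flanking sequence carried from the targeted cells. Of 165 tested genes there, 23 (13.9%) had an unadjusted p under 0.05 for genotype, against 13.5% elsewhere (Fisher's exact test, 2-sided, p = 0.819). Flanking sequence could still differ without changing expression, so the test leaves it open.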
